A study of Mus musculus with 28 samples.

How the data were processed

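The series measured messenger RNA from the cortex of Glt25d2 BacTRAP mice with EAE in 28 libraries, made with poly A enrichment from total RNA and sequenced on a NovaSeq6000: IP and input RNA from healthy mice (5 libraries of each fraction), mice 15 days after immunisation (acute, 5 of each) and mice 30 days after immunisation (chronic, 4 of each). Per the file headers, the deposited values are counts per gene from featureCounts 1.5.1 on exons grouped by gene, with read pairs, without strand, against the Ensembl release 79 annotation of GRCm38, and a further column holds the summed exon length of each gene. The submitters' notes name STAR 2.4 with GRCm38 (mm10) and DESeq2. The command in the header names 36 alignment files, and columns for 28 of them are held, each mapped to a library by its description; the others were not analysed here. Of 43629 genes, 42462 (97.3%) had a symbol in the reference used here. The counts are unstranded, so antisense transcripts add to each other, and reads from paralogs and pseudogenes may be split or lost.

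Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups (minimum count 10, minimum total 15), libraries were scaled with the trimmed mean of M values (TMM), and each contrast was tested with the robust quasi-likelihood F test. Adjusted p-values are Benjamini-Hochberg values, and a gene was called at an adjusted p under 0.05 with no minimum change. There were 11 contrasts. The IP libraries and the input libraries were fitted apart for the 6 contrasts between phases (13914 and 16381 genes), and all 28 libraries together for IP against input in each phase and for the 2 interactions, which test whether the change from healthy differs between IP and input (16580 genes). Log2 changes are those of edgeR ± standard error, and levels are CPM on the TMM-scaled library size, given as mean ± SD. Log CPM used a prior count of 2. Folds against groups with 0 counts used a floor of 3 counts over the group, which covers counting error only.

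The 29 gene lists were written before the data were examined and tested with camera in limma 3.58.1, with the preset inter-gene correlation of 0.01 and again with the correlation estimated from the data, and p-values were adjusted over the lists of a contrast. A list's median is over its measured members, and its calls are given over all genes or, where said, adjusted over the list alone. Genes were named by a rule set in advance: in acute and in chronic IP against healthy the 10 higher and 10 lower genes with the largest absolute log2 change among those called, with an average log2 CPM of at least 1 and groups that do not overlap, and 5 and 5 in the other contrasts. Where fewer than 5 genes met the rule, the 5 with the smallest p were named as having failed the correction. Up to 4 members of each list with the smallest adjusted p were also eligible (2 where none passed), and Sting1, Gpx4 and Colgalt2 were always reported. Genes with provisional symbols were not named. Sting1 was under the filter in the IP fit, so an exact permutation test of its CPM was run.

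The alternatives chosen before the data were examined were DESeq2's size factors, no filter on low counts, the DESeq2 1.42.0 Wald test, a block for the replicate number, all 28 libraries fitted together, only genes higher in IP than in input, each replicate left out in turn, the estimated camera correlation, and healthy libraries split between the 2 phases. The form of the DESeq2 model, a group factor with each pair of groups as a named contrast, was settled after the calls of this form and of a form without an intercept had been seen. In IP against input and in the interactions, the IP and input libraries with the same number were left out together. In addition, 4 further alternatives, voom with library weights, a minimum mean of 50 CPM in IP, leaving out the 4 IP libraries with the fewest genes detected, and an offset for gene length and GC content, were chosen after seeing the data. The exchange of group labels was counted in up to 100 splits of the libraries per contrast.

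The pipeline was tested on simulated data with changes planted in counts drawn like these. In the acute IP contrast it recovered 4 of 89 genes changed 2-fold (4.49%) and 29 of 96 changed 4-fold (30.2%), with 0 false among 33 calls, and in acute input 83.7% and 99.0%, with 10 false among 188 calls. Depth was 17848273 to 27915940 counts per input library and 6198088 to 21229550 per IP library, and the common biological coefficient of variation was 0.101 and 1.06. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.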

Results

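RNA was sequenced from the cerebral cortex of Glt25d2 BacTRAP mice, a line in which ribosomes carry a tag under the control of the Glt25d2 (now Colgalt2) gene, whose expression marks projection neurons of cortical layer 5. Pulling down the tagged ribosomes gives an immunoprecipitated fraction (IP), meant to enrich the RNA that these neurons were translating. The RNA before the pulldown is the input. Mice were healthy, or had experimental autoimmune encephalomyelitis (EAE), a model of multiple sclerosis induced by immunisation with the myelin peptide MOG35-55, and were taken in the acute phase at 15 days or in the chronic phase at 30 days. The 28 libraries fell into 6 groups: 5 healthy, 5 acute and 4 chronic libraries of each of the 2 fractions. The labels do not say that the libraries of a group came from separate mice, so the p-values measure the spread between libraries, which may be technical. Totals ran from 17848273 to 27915940 counts per input library and from 6198088 to 21229550 per IP library.

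The IP libraries held fewer genes than the input libraries, and the lowest IP totals lay below every input total. At least 1 count was found for 20714 to 21734 genes per input library and for 9566 to 17995 per IP library. Of 4410 genes with 0.5 to 5 CPM (counts scaled to the size of the library) in input, 99.1% to 100% had a read in each input library and 12.6% to 93.0% in each IP library. The Pearson correlation of log CPM across genes between libraries of a group was 0.986 to 0.992 in input and 0.669 to 0.960 in IP, and genes are not independent replicates. The common biological coefficient of variation was 0.101 in input and 1.06 in IP. All 52 pairs of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom of 4.24 to 178, so every library counted as 1 replicate.

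**Figure D1:**
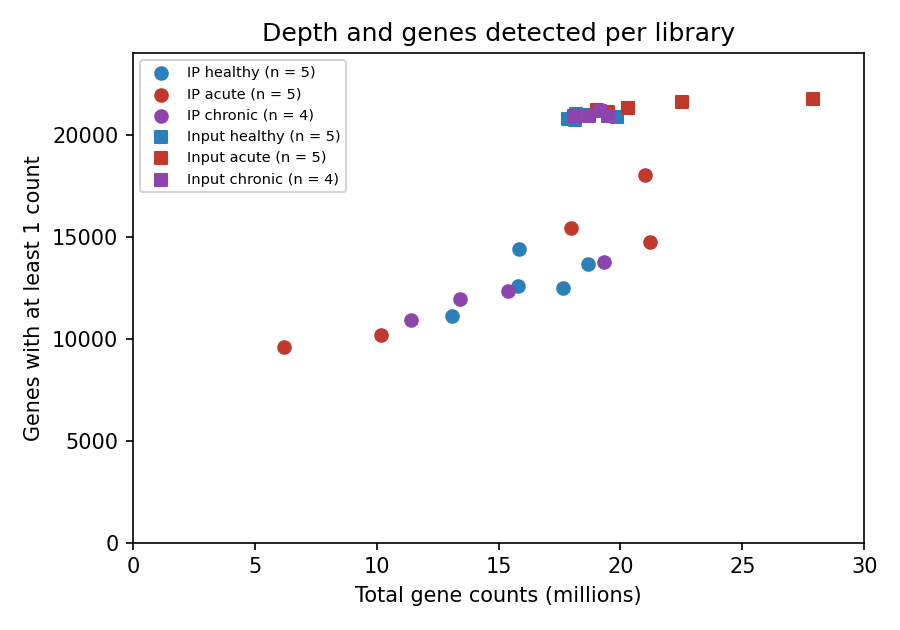
Total gene counts per library (x axis) against the number of genes with at least 1 count (y axis), with 1 point per library, circles for IP and squares for input, coloured by phase. The 14 input libraries lie between 20714 and 21734 genes, and the 14 IP libraries between 9566 and 17995.

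The first comparison asked what the pulldown enriched in healthy mice. Markers of layer 5 projection neurons were higher in IP, with 7 of 16 members higher, 1 lower and a median log2 ratio of 0.41. Among them were Pou3f1 (log2 ratio 1.97 ± 0.20 SE, adjusted p = 4.16e-08), Fezf2, the transcription factor that specifies these neurons (1.87 ± 0.20), Crym (1.41 ± 0.16) and the heavy neurofilament gene Nefh (0.87 ± 0.13), each with n = 5 per fraction. Lower in IP were Mobp, a myelin gene of oligodendrocytes (-1.72 ± 0.23), the astrocyte glutamate transporter Slc1a2 (-1.33 ± 0.27) and Rasgrf2, a marker of upper layers (-0.87 ± 0.13). Colgalt2, the driver of the tag (chromosome 1, 152399830 to 152510695, plus strand, GRCm38), had 68.4 ± 20.4 CPM in IP and 53.1 ± 2.41 in input (mean ± SD), a log2 ratio of 0.36 ± 0.17 that failed the correction (adjusted p = 0.130).

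In all, 1194 genes were higher and 2393 lower in IP than in input among 16580 tested with edgeR's quasi-likelihood test, and the median log2 ratio of all genes was -0.23. The highest ratios under the naming rule were those of Atg7, the E1-like enzyme of autophagy (4.78 ± 0.18), the synaptic exchange factor Kalrn (3.82 ± 0.23), the ubiquitin ligase Ubr3 (3.30 ± 0.20) and the adaptor Sh2d3c (3.25 ± 0.19). Sox17, an endothelial transcription factor, also met the rule (3.34 ± 1.12, adjusted p = 0.0293), but it passed in 0 of the 5 fits that left out 1 replicate. Firre, Exph5, Zc3h11a, Adamts20 and Sned1 had 0 counts in all 5 healthy IP libraries. Against a floor of 3 counts over the group they were at least 200.1-fold, 189.6-fold, 174-fold, 174-fold and 170.1-fold lower in IP. The floor covers counting error only, not the spread between IP libraries.

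Of the 29 gene lists, 10 passed the camera test with the preset correlation in healthy mice. The layer 5 markers kept their call with an estimated correlation (adjusted p = 1.61e-07 preset and 0.0229 estimated), as did the heat shock response (8 of 14 higher, median 0.96, adjusted p = 1.20e-12 preset and 0.0246 estimated), whose chaperones Hspa8 and Hsp90aa1 stood at 1.39 ± 0.13 and 1.02 ± 0.08. Proteasome subunits (22 of 31 higher, median 0.68, adjusted p = 2.12e-16) and nuclear-encoded oxidative phosphorylation (19 of 48, 0.50, adjusted p = 2.12e-16) were higher with the preset correlation. Their adjusted p = 0.161 and 0.456 with an estimated correlation. Of 12 mitochondrially encoded genes 9 were lower (median -2.53, adjusted p = 3.99e-09, and adjusted p = 0.137 with an estimated correlation). Among these were mt-Cytb at -2.83 ± 0.28 and mt-Co1 at -3.13 ± 0.35. Voltage-gated ion channels (10 of 26 lower, median -0.72, adjusted p = 0.0307) and oligodendrocyte markers (6 of 12, -1.32, adjusted p = 0.0117) were lower by the preset test. Their adjusted p = 0.798 and 0.601 with an estimated correlation.

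In acute EAE, 1420 genes were higher and 1677 lower in IP than in input. The layer 5 markers were again higher (8 of 16, none lower, median 0.68, adjusted p = 5.42e-11 preset and 0.00172 estimated), with Nefh at 1.80 ± 0.13 and Fezf2 at 2.07 ± 0.20. Colgalt2 was higher at 0.63 ± 0.17 (81.9 ± 13.6 CPM against 53.0 ± 0.536, n = 5 each, adjusted p = 0.00643), and it passed in 4 of 5 fits that left out 1 replicate, the exception being acute 2 (adjusted p = 0.0504). All 12 mitochondrially encoded genes were lower (median -4.45, adjusted p = 2.96e-16 preset and 0.0181 estimated), as were 43 of 80 cytosolic ribosomal protein genes (median -0.85, adjusted p = 9.76e-11 preset and adjusted p = 0.579 with an estimated correlation). The NMDA receptor subunit Grin1 was higher at 1.70 ± 0.17 and Rps20 lower at -1.69 ± 0.27. The median log2 ratio of all genes was -0.36.

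In chronic EAE, 1449 genes were higher and 3315 lower in IP, with 4 libraries per fraction and a median of -0.32 over all genes. Layer 5 markers (7 of 16 higher, none lower, median 0.50, adjusted p = 1.05e-07 preset and 0.0108 estimated), the heat shock response (8 of 14, 1.08, 4.79e-15 and 0.0108) and mitochondrially encoded genes (12 of 12 lower, -4.37, 1.13e-12 and 0.0446) passed under both correlations. Hsph1, a chaperone of the HSP110 family, stood at 1.88 ± 0.12, Crym at 1.61 ± 0.18, Nefh at 1.75 ± 0.15 and the respiratory complex III subunit Uqcrc1 at 1.70 ± 0.17. Colgalt2 was higher at 0.75 ± 0.19 (86.2 ± 14.2 CPM against 51.3 ± 2.84, adjusted p = 0.00295). The noncoding RNA Ftx, Zbtb37, Fgfbp3, the DNA demethylation enzyme Tet1 and Creb3l2 had 0 counts in all 4 chronic IP libraries, at least 274.5-fold, 253-fold, 226-fold, 215-fold and 201-fold lower than in input. Here too the floor covers counting error only.

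In the whole cortex, the input comparison of acute EAE with healthy mice asked which transcripts changed. Interferon response genes rose together: all 29 measured members were higher, with a median log2 change of 3.52 (adjusted p = 7.15e-106 preset and 0.00409 estimated). They included Rtp4 at 3.52 ± 0.24 SE, the antiviral enzyme Oas1a at 4.42 ± 0.36, Ifi27 at 1.31 ± 0.09 and the T cell attractant Cxcl10 at 7.46 ± 0.66, from 0.0864 ± 0.0488 CPM in healthy mice to 16.4 ± 7.78 in acute EAE (mean ± SD, n = 5 each). All 14 genes of MHC class I antigen presentation were higher (median 2.44, adjusted p = 2.26e-36 preset and 0.0127 estimated), among them the transactivator Nlrc5 (4.68 ± 0.29) and the immunoproteasome subunit Psmb9 (4.28 ± 0.29). For MHC class II it was 6 of 7 (median 3.96, 9.58e-15 and 0.0141), with the invariant chain gene Cd74 at 4.65 ± 0.51 and H2-Aa at 5.06 ± 0.56.

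Leukocyte, microglial and astrocyte genes were also higher in acute input. Infiltrating leukocyte markers had 8 of 11 members higher (median 1.81, adjusted p = 8.53e-09 preset and 0.0141 estimated), with the lymphocyte surface protein gene Cd52 at 3.54 ± 0.32 and the neutrophil gene S100a8 at 4.73 ± 0.57. Microglia markers had 8 of 12 higher and 1 lower (median 1.14, adjusted p = 2.23e-08, and adjusted p = 0.169 with an estimated correlation), such as the complement gene C1qb (2.44 ± 0.32), Tyrobp (1.91 ± 0.22) and Aif1 (1.38 ± 0.16). Of 12 astrocyte markers 4 were higher (median 0.53, adjusted p = 2.79e-05, and adjusted p = 0.180 with an estimated correlation), led by the intermediate filament gene Gfap at 2.20 ± 0.15, from 81.5 ± 7.74 to 374 ± 48.9 CPM. The NF-kB, cytokine and acute phase list had 15 of 16 higher (median 1.47, adjusted p = 1.57e-24 preset and 0.00318 estimated), and the glucocorticoid response 12 of 15 (0.75, 1.76e-15 and 0.0141), including the metallothionein gene Mt1 at 0.75 ± 0.07. In the STING pathway list 6 of 14 members were higher (median 0.20, adjusted p = 3.75e-05 preset and 0.0141 estimated), led by the DNA sensor gene Ifi204 (5.35 ± 0.37). Ribosomal protein genes (67 of 80 higher, median 0.24, 1.85e-26) and nuclear-encoded oxidative phosphorylation (26 of 48, 0.14, 1.16e-06) rose by the preset test, with adjusted p = 0.169 and 0.361 with an estimated correlation.

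Neuronal genes made up part of the lower side. Glutamate receptor and postsynaptic genes had 8 of 23 members lower and none higher (median -0.16, adjusted p = 0.00183, and adjusted p = 0.169 with an estimated correlation), with the receptor subunits Gria4 at -0.40 ± 0.05 and Grin2b at -0.33 ± 0.07. Upper layer and layer 6 markers had 5 of 13 lower and 1 higher (median -0.16, adjusted p = 0.0132, and adjusted p = 0.149 with an estimated correlation), with Rorb at -0.63 ± 0.11 and Calb1 at -0.29 ± 0.04. In all, 1823 genes were higher and 1407 lower among 16381 tested, of which 559 and 49 changed by more than 2-fold. The gene highest by the naming rule, Lcn2, a secreted acute phase protein, had 0 counts in every healthy library and was at least 149-fold higher. The T cell attractants Cxcl9 and Ccl5 and the myeloid gene Plac8 rested on 1 to 3 healthy counts, with ratios of 564 (95% counting interval 101 to 22310), 308 (105 to 1497) and 154 (52.5 to 749.6), and such intervals and floors cover counting error only. On the lower side stood the protease inhibitor gene Serpinb1a (-1.43 ± 0.18), Samd3 (-1.36 ± 0.22), Dach1 (-1.01 ± 0.19), Kcnq1ot1 (-0.95 ± 0.17) and Cdr1 (-0.95 ± 0.19), the last pair of which overlap antisense transcripts that unstranded counts cannot separate. All the genes named here for acute input kept their calls in each of 10 fits that left out 1 library.

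The other 16 lists did not pass the preset test in acute input. Their medians were -0.04 for layer 5 markers (adjusted p = 0.783, 1 higher and 3 lower of 16), 0.01 for inhibitory neuron markers (0.955), -0.10 for oligodendrocyte markers (0.545), 0.04 for oligodendrocyte precursor markers (0.955), 0.17 for endothelial and mural cell markers (0.583) and -0.70 for red blood cell markers (0.383). The unfolded protein and integrated stress response stood at 0.14 (adjusted p = 0.0665, 2 of 23 higher), ferroptosis and antioxidant defence at 0.09 (0.0513), the heat shock response at -0.02 (0.955), proteasome subunits at 0.02 (0.564) and mitochondrially encoded genes at 0.02 (0.955). Presynaptic genes stood at -0.10 (0.0908), voltage-gated ion channels at -0.09 (0.0665), immediate early genes at -0.22 (0.184), the axon injury response at 0.06 (0.955) and cholesterol biosynthesis at -0.03 (0.564). Median, mean and test differed in sign for the inhibitory neuron, heat shock and mitochondrially encoded lists. In the ferroptosis list 7 of 23 genes were higher, among them the ferritin gene Fth1 (0.38 ± 0.04) and the heme-degrading enzyme gene Hmox1 (0.92 ± 0.12).

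By the chronic phase the input libraries still differed from healthy in 382 genes that were higher and 67 that were lower. Interferon response genes had 23 of 29 members higher (29 when adjusted over the list alone, median 1.72, adjusted p = 1.98e-75 preset and 0.00726 estimated). MHC class I had 9 of 14 higher (median 1.94, 2.81e-35 and 0.00921), with Nlrc5 at 3.48 ± 0.32 and H2-Q4 at 3.76 ± 0.44, MHC class II had 6 of 7 (3.31, 2.04e-20 and 0.00726), with Cd74 at 4.05 ± 0.53, and leukocyte markers had 6 of 11 (1.90, 9.20e-12 and 0.00726), with Cd52 at 2.51 ± 0.35. The NF-kB and acute phase list had 8 of 16 (1.10, 3.27e-23 and 0.00566), and the STING pathway 2 of 14 (0.12, 2.55e-05 and 0.0116), 1 of them Ifi204 at 3.84 ± 0.42. Microglia markers (3 of 12 higher, median 0.78, 4.63e-11), astrocyte markers (2 of 12, 0.37, 3.41e-07) with Gfap at 1.27 ± 0.15, and oligodendrocyte markers (1 of 12, 0.31, 0.000129) with Mobp at 0.31 ± 0.06 rose by the preset test. Their adjusted p = 0.138, 0.138 and 0.219 with an estimated correlation.

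Immediate early genes, which respond to neuronal activity, were lower as a list in chronic input (0 of 17 called, 5 when adjusted over the list alone, all 17 negative, median -0.61, adjusted p = 9.53e-09, and adjusted p = 0.206 with an estimated correlation). The largest single changes were those of Lcn2, at least 95-fold higher against 0 healthy counts, of Cxcl9, Ccl5 and Plac8 with ratios of 183 (95% counting interval 32.4 to 7278), 85.2 (28.8 to 416.5) and 41.0 (13.6 to 202), and of the interferon-inducible GTPase gene Tgtp2 (5.32 ± 0.86). Lower were the troponin gene Tnnc1 (-0.69 ± 0.13), Foxo6 (-0.58 ± 0.09) and Dtl (-0.57 ± 0.09). The doublecortin gene Dcx (-0.43 ± 0.10, adjusted p = 0.0162) lost its call without chronic 4 (0.0617), and C1qb (1.64 ± 0.33) passed in 6 of 9 fits that left out 1 library. Without chronic 4, 250 genes were called in place of 449, and DESeq2 called 687.

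Between the chronic and the acute phase, 483 genes were higher and 776 lower in chronic input. All 29 interferon response genes were lower in the chronic phase (median -1.72, adjusted p = 2.85e-56), with Isg15 at -2.58 ± 0.33, Ifi44 at -2.48 ± 0.48, Gbp2 at -2.36 ± 0.32 and Cxcl10 at -2.63 ± 0.43, although the list reached only adjusted p = 0.0600 with an estimated correlation. Mx1, another interferon-induced gene, stood at -2.29 ± 0.32. MHC class I (6 of 14 lower, median -0.67, 1.50e-12) and the glucocorticoid response (9 of 15, -0.59, 2.39e-13) fell by the preset test, with adjusted p = 0.162 and 0.0648 with an estimated correlation. Gfap was lower at -0.93 ± 0.15 and the cell cycle inhibitor gene Cdkn1a at -0.71 ± 0.10. Higher were Serpinb1a (1.31 ± 0.19), Cdr1 (1.19 ± 0.19), the oligodendrocyte enzyme gene Aspa (0.51 ± 0.10), the potassium channel gene Kcnq3 (0.32 ± 0.06) and the microglial receptor gene P2ry12 (0.70 ± 0.16). Oligodendrocyte markers had 3 of 12 higher (median 0.36, 8.10e-06), glutamate receptor genes 5 of 23 (0.12, 3.44e-05) and ion channels 7 of 26 (0.16, 5.55e-06). Their adjusted p = 0.213, 0.162 and 0.213 with an estimated correlation, and no list passed in this comparison with an estimated correlation. Without chronic 2, 784 genes were called in place of 1259.

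**Figure D2:**
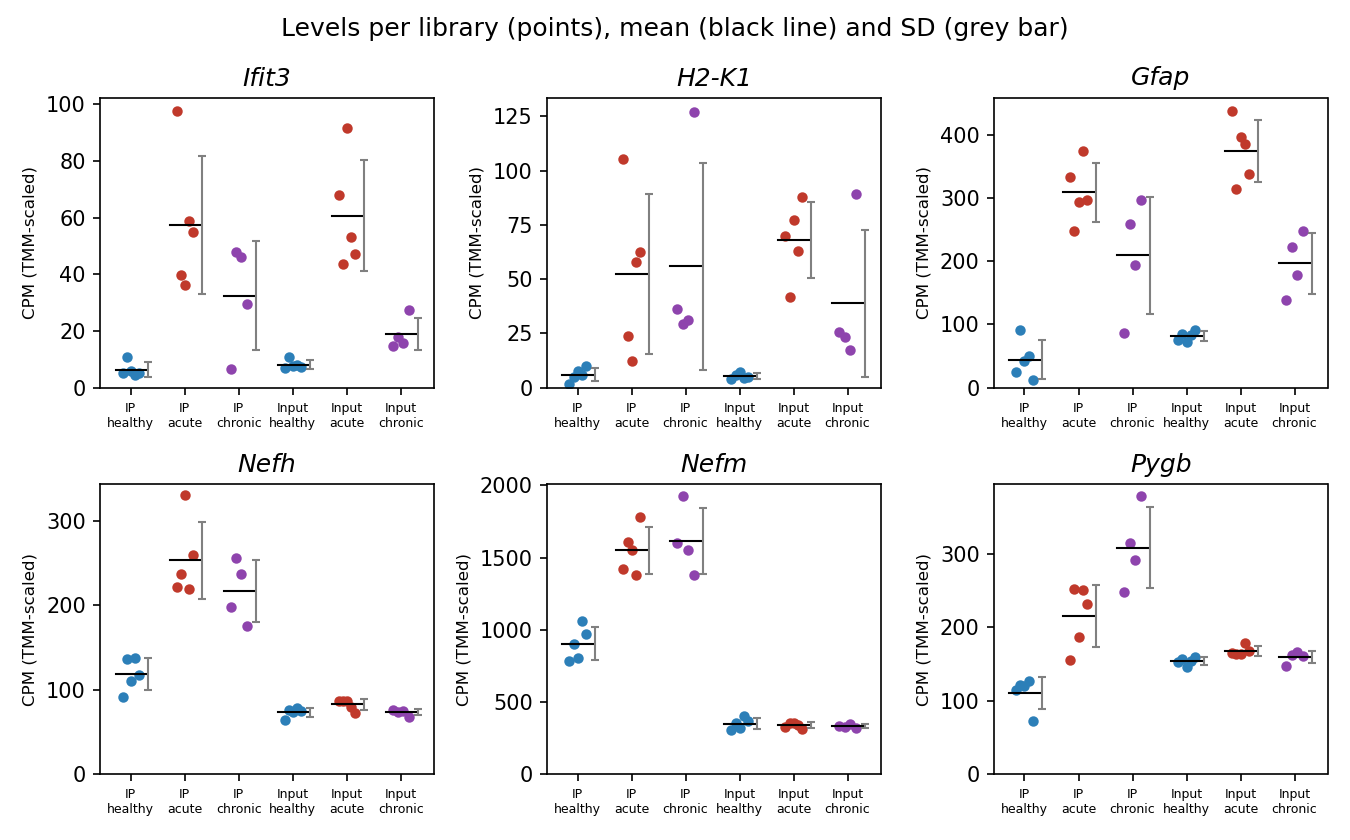
CPM per library (points, y axis linear from 0), group mean (black line) and SD (grey bar) of 6 genes in the 6 groups on the x axis. Ifit3 rises from 6.25 in healthy to 57.3 in acute IP, Nefm stands at 904 in healthy IP and 1550 in acute IP but at 347 and 338 in input, and Pygb at 111 in healthy IP and 309 in chronic IP.

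In the IP fraction of acute EAE, the question was which transcripts changed in the RNA pulled down with the tagged ribosomes. The interferon-induced gene Ifit3 rose from 6.25 ± 2.63 to 57.3 ± 24.4 CPM (mean ± SD, n = 5 each, log2 change 3.19 ± 0.50 SE, adjusted p = 0.0169). The MHC class I gene H2-K1 was higher at 3.15 ± 0.60 (0.0497). Gfap, on the astrocyte marker list, was higher at 2.81 ± 0.44 (0.0282). Its change in IP did not pass as different from that in input (edgeR interaction 0.61 ± 0.45, adjusted p = 0.799). Whether RNA of astrocytes accounts for the Gfap call was not tested. Nefh and Nefm, which encode neurofilament subunits, were higher, Nefh from 118 ± 19.3 to 254 ± 45.7 CPM (1.10 ± 0.18, 0.0169) and Nefm from 904 ± 116 to 1550 ± 161 (0.78 ± 0.13, 0.0169), as were the kinase genes Lmtk3 (1.11 ± 0.21, 0.0497) and Mast3 (0.81 ± 0.15, 0.0387). The mitochondrially encoded mt-Cytb was lower at -1.57 ± 0.30 (0.0497). In all, 8 genes were higher and 1 lower among 13914 tested with edgeR, while 871 genes had an unadjusted p under 0.05. Reads of H2-K1 can be shared with other class I genes, those of Ifit3 with Ifit3b, and those of mitochondrially encoded genes with nuclear copies.

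As lists, interferon response genes rose in acute IP (2 of 29 called over all genes and 17 adjusted over the list alone, 27 positive, median 2.88, adjusted p = 8.66e-32 preset and 0.000891 estimated). MHC class I genes rose too (1 of 14 called, 2 over the list alone, median 1.94, 3.48e-08 and 0.0210). Mitochondrially encoded genes fell (1 of 8 called, 5 over the list alone, median -1.62, 1.84e-11 and 0.0228). Mitochondrial reads made up 0.030% to 0.079% of counts in healthy, 0.011% to 0.024% in acute and 0.017% to 0.032% in chronic IP libraries. Whether the purity of the pulldown differed between phases was not tested, which bears on this list, the layer 5 list, Nefh and Nefm. Cytosolic ribosomal protein genes had 0 of 77 members called but 76 negative (median -0.56, 1.65e-22, and adjusted p = 0.339 with an estimated correlation), such as Rpl9 at -1.02 ± 0.31 and Rps3 at -0.69 ± 0.22. Nuclear-encoded oxidative phosphorylation (median -0.31, 1.42e-05), proteasome subunits (-0.25, 0.00683), MHC class II (2.0, 0.000154), the NF-kB list (0.81, 0.000401), presynaptic genes (0.19, 0.000732), astrocyte markers (0.24, 0.00146) and layer 5 markers (0.25, 0.0121) also passed the preset test. With an estimated correlation these had adjusted p = 0.661, 0.668, 0.108, 0.247, 0.339, 0.339 and 0.339. Markers of other cells measured beside them had a median of 0.37 for microglia (adjusted p = 0.577), -0.75 for endothelial and mural cells (0.289), -0.87 for 5 measured leukocyte markers (0.733), -0.26 for oligodendrocytes (0.195) and 0.33 for oligodendrocyte precursors (0.589). Without the 4 IP libraries with the fewest genes detected, a setting chosen after the data were seen, microglia markers (median 0.71, adjusted p = 0.0395) and oligodendrocyte precursor markers (1.08, 0.0153) passed the preset test.

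In acute IP, Ifit3 and Nefh passed in 7 of the 10 fits that left out 1 library, Nefm in 6, Gfap in 4, H2-K1, Mast3 and mt-Cytb in 2, and Lmtk3 in 1. The count was 50 without acute 1, 3 without acute 2, 4 without acute 4, 1 without acute 5, 2 without healthy 1, 1 without healthy 3 and 5 without healthy 5. With an offset for gene length and GC content, chosen after the data were seen, Nefm went from 0.78 ± 0.13 to 0.44 ± 0.13, Mast3 from 0.81 ± 0.15 to 0.44 ± 0.13, Lmtk3 from 1.11 ± 0.21 to 0.65 ± 0.21, Nefh from 1.10 ± 0.18 to 0.82 ± 0.15 and mt-Cytb from -1.57 ± 0.30 to -0.59 ± 0.35. These 5 calls ended because the log2 change shrank towards 0, and that of Gfap (2.81 ± 0.44 to 2.61 ± 0.44, adjusted p = 0.0546) ended at the threshold.

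**Figure D3:**
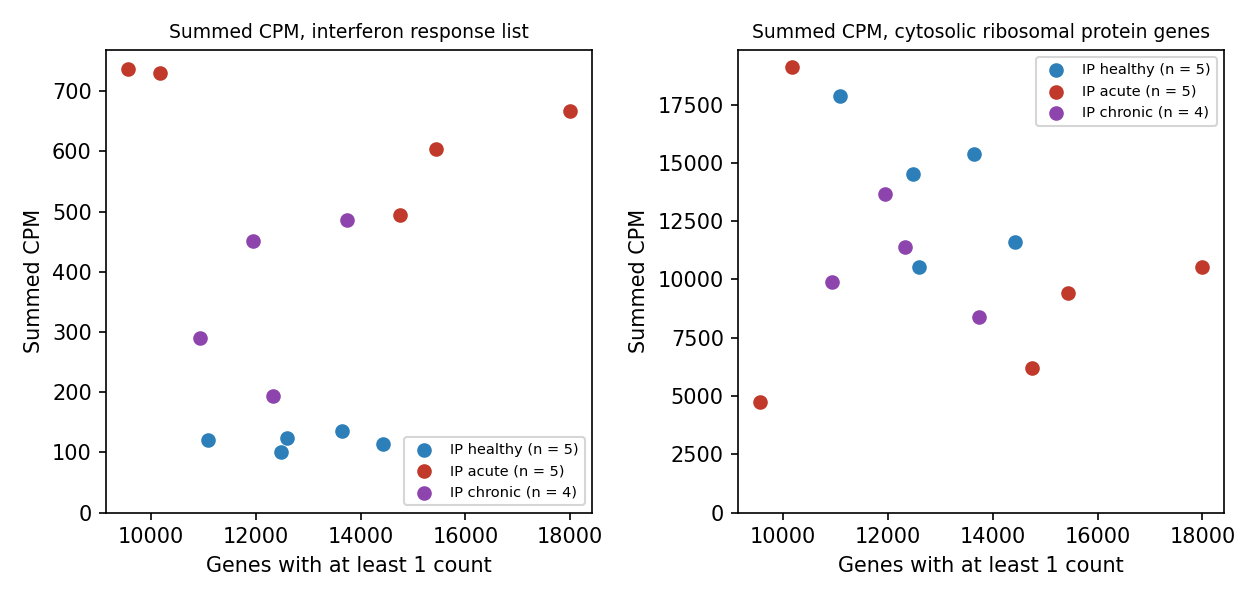
Genes with at least 1 count (x axis) against the summed CPM of the interferon response list and of the ribosomal protein genes (y axes) in the 14 IP libraries. The interferon sum is 494 to 737 in acute and 99.8 to 135.5 in healthy libraries, and the ribosomal sum 4758 to 19120 and 10540 to 17870.

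In the IP fraction of chronic EAE, 25 genes were higher than in healthy mice and 1 was lower. Pygb, the brain form of glycogen phosphorylase, went from 111 ± 22.3 CPM (SD, n = 5) to 309 ± 55.2 (n = 4, log2 change 1.48 ± 0.20 SE, adjusted p = 0.00484), pyruvate carboxylase Pcx from 48.7 ± 7.57 to 120.3 ± 17.02 (1.31 ± 0.22, 0.00768), the mitochondrial aldehyde dehydrogenase Aldh2 from 118 ± 17.7 to 259 ± 56.7 (1.13 ± 0.18, 0.00695) and the glycolytic enzyme Aldoc, which is also on the astrocyte marker list, from 659.8 ± 123 to 1417 ± 367 (1.10 ± 0.19, 0.0110). Lrpprc, a regulator of mitochondrial messenger RNA, was higher at 1.35 ± 0.23 (0.00873). H2-K1 was again higher (3.25 ± 0.61, 0.0267). Further higher were the ubiquitin ligase gene Ubr4 (1.39 ± 0.28), Bcas3 (1.22 ± 0.22), the autotaxin gene Enpp2 (1.21 ± 0.25), the sodium-calcium exchanger Slc8a2 (1.14 ± 0.23) and Hsph1 (0.79 ± 0.14, 0.0166). Gad1, which makes GABA and is on the inhibitory neuron marker list, was also higher (0.97 ± 0.19, 0.0271). Only Jpt1 was lower (-1.11 ± 0.22, 0.0325). Glial markers rose in the same libraries, and whether RNA of other cells adds to these calls was not tested.

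Of 13914 genes 26 passed in chronic IP, and 1494 had an unadjusted p under 0.05. Interferon response genes rose by the preset test (1 of 29 called, 11 over the list alone, median 1.99, adjusted p = 2.61e-09, and adjusted p = 0.121 with an estimated correlation), as did MHC class I (1 of 14, 1.90, 0.000127, estimated adjusted p = 0.178). Mitochondrially encoded genes (0 of 8 called, 3 over the list alone, median -1.20, 6.05e-05), immediate early genes (0 of 17, 16 negative, -0.84, 1.41e-05) and ribosomal protein genes (0 of 77, 75 negative, -0.42, 9.94e-08) fell by the preset test, with adjusted p = 0.287, 0.287 and 0.657 with an estimated correlation. Egr1 (-0.87 ± 0.19, 0.0546) and mt-Nd4 (-1.79 ± 0.41, 0.0693) failed the correction as single genes. Markers of glia rose in the same libraries, astrocytes with a median of 1.04 (adjusted p = 0.000304), oligodendrocytes with 0.70 (0.0187) and microglia with 1.51 (0.0291), and these had adjusted p = 0.304, 0.554 and 0.657 with an estimated correlation. The heat shock response (1 of 14 called, median 0.26, 0.0291), the unfolded protein response (0 of 21, 0.08, 0.0187), the NF-kB list (0 of 11, 0.41, 0.0162) and MHC class II (0 of 5, 2.13, 0.0393) passed only the preset test. Their adjusted p = 0.602, 0.287, 0.431 and 0.432 with an estimated correlation.

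Pygb, Pcx and Aldh2 passed in all 9 fits that left out 1 library of the chronic comparison, with 6 further genes. Lrpprc passed in 7, Aldoc and Bcas3 in 5, Hsph1 in 4, H2-K1 and Gad1 in 3, Ubr4, Slc8a2 and Jpt1 in 2, and Enpp2 in 1. The count was 43 without chronic 1, 14 without chronic 2, 12 without chronic 3, 13 without chronic 4, 10 without healthy 1, 9 without healthy 3 and 13 without healthy 5. In voom with library weights, chosen after the data were seen, H2-K1 had adjusted p = 0.215.

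**Figure D4:**
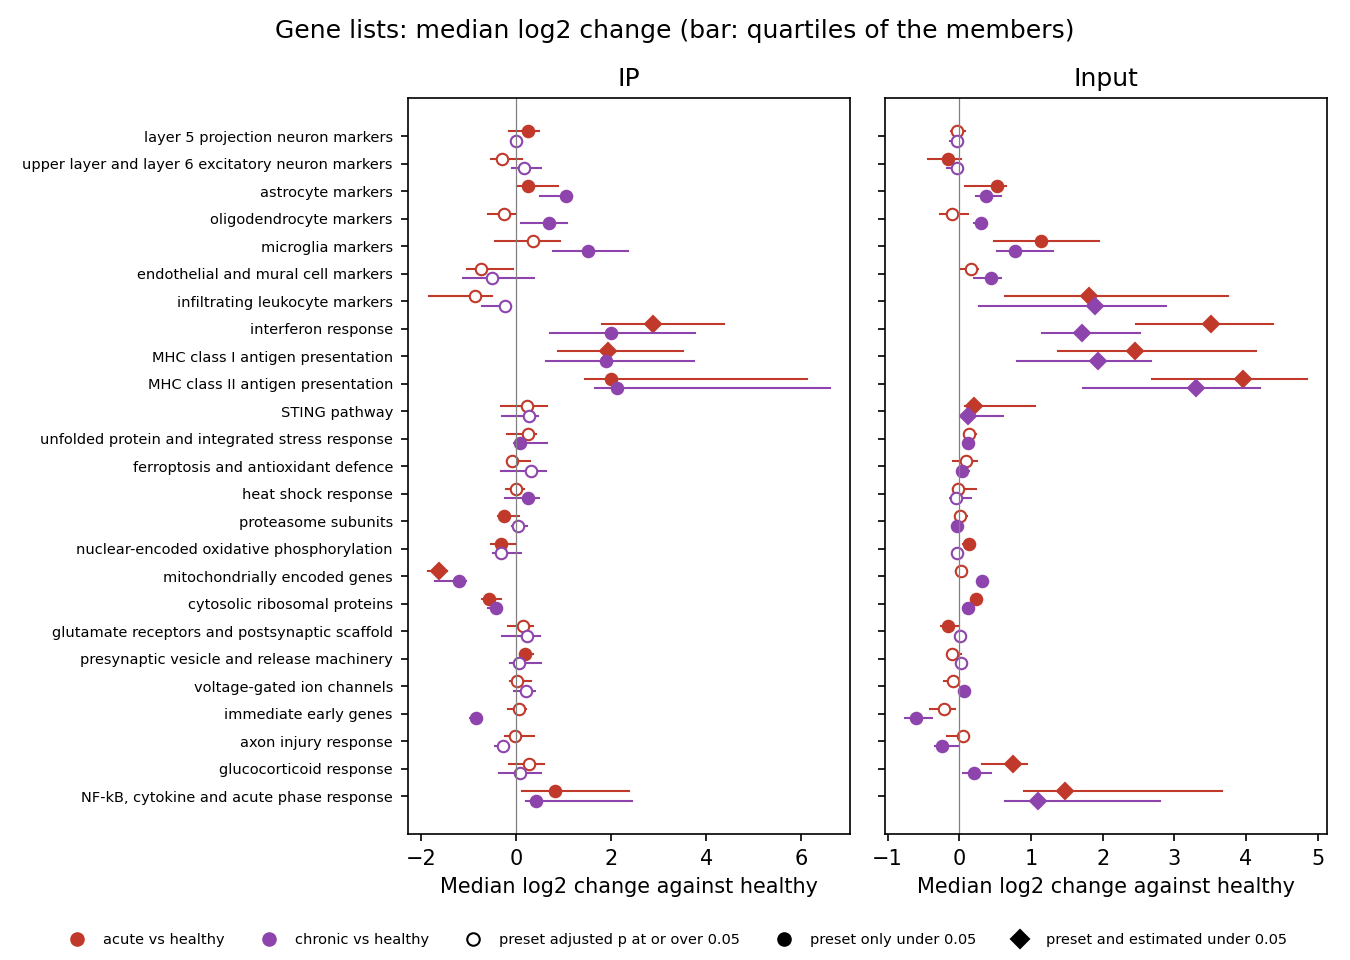
Median log2 change against healthy (x axis) of 25 gene lists (y axis) in IP (left) and input (right), red for acute and purple for chronic, with bars from the lower to the upper quartile of the members. Filled circles passed the camera test with the preset correlation only, diamonds also with the estimated one, and open circles neither. Interferon genes stand at 2.88 in acute IP and 3.52 in acute input.

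Between the chronic and acute phases in IP, no gene passed edgeR's test among 13914, while 1145 had an unadjusted p under 0.05, DESeq2 called 225 and voom with library weights, chosen after the data were seen, 60. The genes with the smallest p failed the correction, each with adjusted p = 0.122: Lrpprc (1.30 ± 0.23), the cyclin-dependent kinase 5 activator Cdk5r2 (-0.90 ± 0.17), Sh3bp1 (-0.93 ± 0.18), Klhl9 (1.19 ± 0.24) and the phosphofructokinase Pfkp (0.86 ± 0.17). Interferon response genes had 27 of 29 members negative (median -0.96, adjusted p = 1.01e-05), immediate early genes 13 of 17 (-0.89, 1.01e-05), oligodendrocyte markers 9 of 12 positive (1.02, 6.61e-05) and proteasome subunits 26 of 31 positive (0.33, 1.01e-05). Their adjusted p = 0.332, 0.421, 0.421 and 0.657 with an estimated correlation, and no list passed with it.

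Whether the change in IP differed from that in input was tested as an interaction over all 28 libraries. In the acute phase (acute vs healthy change, IP minus input) edgeR called 1 gene, Nefm, which rose by 0.82 ± 0.14 more in IP than in input (adjusted p = 0.0492 among 16580 genes). DESeq2 called 611. Nefm passed in 2 of 10 fits that left out 1 replicate. It lost its call with a block for the number that IP and input libraries share. The count was 287 without acute 1, 6 without healthy 4 and 0 without acute 2, 3, 4 or 5 or healthy 1, 3 or 5. Nefh (0.93 ± 0.18), Mast3 (0.76 ± 0.14), the adaptor gene Ap3d1 (0.83 ± 0.18) and Sag, read in 4 of 5 acute and 0 of 5 healthy IP libraries, failed with adjusted p = 0.0706. Ribosomal protein genes had a lower change in IP than in input (median -0.77, 79 of 80 negative, adjusted p = 1.51e-35), as did mitochondrially encoded genes (-1.77, 2.15e-11). Their adjusted p = 0.448 and 0.132 with an estimated correlation.

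In the chronic phase 105 genes had a higher and 65 a lower change in IP than in input. Fewer were called with a block for the number that IP and input libraries share. Chaperones were among them, Hsph1 at 0.97 ± 0.16 (adjusted p = 0.00261) and Hsp90aa1 at 0.65 ± 0.12 (0.00823), with the proteasome subunit Psmd1 at 1.09 ± 0.18 (0.00261) and Lrpprc at 1.51 ± 0.25 (0.00261), and each of these passed in all 9 fits that left out 1 replicate. Gad1 stood at 1.03 ± 0.21 (0.0170, and 0.0653 without chronic 4) and mt-Nd4 at -2.07 ± 0.46 (0.0277, passing in 4 of 9 such fits). Ccdc153, Fgfbp3 and Uvssa, at 9.90 ± 9.59, 7.60 ± 4.22 and 7.28 ± 3.73 CPM (SD, n = 5) in healthy IP, had 0 counts in all 4 chronic IP libraries and kept their calls in all 9 fits. Leaving out 1 replicate cannot show whether these zeros came from sampling of few molecules, which was not tested for these genes. Nor does it lift the limit of the shared dispersion, which holds for all calls of this contrast. The heat shock list had 3 of 14 members higher (median 0.21, adjusted p = 0.00735, and adjusted p = 0.839 with an estimated correlation). The count was 148 without chronic 1, and 56, 43 and 69 without chronic 2, 3 and 4. It was 43, 63, 62, 101 and 68 without healthy 1 to 5.

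Nefm and H2-K1 were among the genes called higher in both acute and chronic IP, 3 in all against 0.0144 for independent lists, and 0 genes were called in opposite directions. Both comparisons use the 5 healthy libraries. With healthy libraries split between them, each phase had a median of 0 calls in 20 draws, so those draws do not show whether the sharing rests on the controls. Over 5587 genes at a log2 CPM of at least 5, the correlation of the changes was 0.539, against 0.473 (0.448 to 0.495) with simulated unchanged groups, and their covariance 0.0989 against 0.0682, a difference of 0.0308. In input, 406 genes were called in the same direction in both phases (365 higher and 41 lower, against 42.5 and 5.76 for independent lists) and 3 in opposite directions. The covariance there was 0.0151 against 0.00346 simulated, a difference of 0.0117, and split controls gave a median of 122 shared calls (8 to 212).

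Of the 1823 genes higher in acute input, 1530 were tested in IP, where 4 were called higher and 0 lower. Of the 1407 lower in acute input, 1337 were tested in IP, and none of the 9 acute IP calls was among them. Among those at a log2 CPM of at least 5 in IP, 55.0% of 680 higher and 63.7% of 729 lower genes had the same sign in IP. Of the chronic input calls, 3 of 273 higher genes tested in IP were called in the same direction, and none of the 26 chronic IP calls was among the 66 lower genes tested.

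Sting1, the adaptor of cytosolic DNA sensing that the title of the series names (annotated as Tmem173, chromosome 18, 35733678 to 35740554, minus strand), was read thinly. In input it rose from 0.649 ± 0.255 CPM in healthy mice (mean ± SD, n = 5) to 2.14 ± 0.619 in acute EAE (n = 5, log2 change 1.71 ± 0.31, adjusted p = 0.000631) and to 1.71 ± 0.720 in chronic EAE (n = 4, 1.39 ± 0.34, adjusted p = 0.0287), the latter in 5 of 9 fits that left out 1 library. The exceptions were chronic 4 (0.168), healthy 1 (0.0616), healthy 2 (0.0765) and healthy 4 (0.0720). In IP it was under the filter on low counts, with 0 counts in all 5 healthy libraries, 11 and 3 counts in acute 4 and 5 and 0 in the other acute libraries, and 91, 205 and 56 counts in chronic 2, 3 and 4 and 0 in chronic 1. Pooled, chronic IP held 5.92 CPM, at least 159.7-fold above the healthy floor of 0.0370 CPM (3 counts over the group), and 3.06 CPM, at least 82.5-fold, without chronic 3, which held 205 of the 352 counts. Leaving out any other library of these 2 groups gave at least 122.9-fold to 215.4-fold. A two-sided exact permutation test gave p = 0.0476 (Benjamini-Hochberg adjusted 0.0714 over 6 tests) for chronic against healthy IP, where the smallest possible p was 0.00794, and exact p = 0.444 for acute against healthy. For chronic against healthy IP, adjusted p = 0.236 with no filter in edgeR, 0.0103 in DESeq2 and 0.00116 with all 28 libraries fitted together, the setting in which Sting1 lost both input calls (adjusted p = 1). The interaction called Sting1 in the chronic phase (adjusted p = 0.0413, and 0.0730 with no filter), but only in 1 of 9 fits that left out 1 replicate, the one without chronic 1, and not in the acute phase (0.503). With a block for the number that IP and input libraries share, Sting1 had adjusted p = 0.550 in the chronic interaction. Against input, Sting1 was at least 17.5-fold lower in healthy IP (0 against 60 counts, adjusted p = 0.00351), and the ratio failed the correction in the acute (-3.54 ± 1.27, 0.0524) and chronic phases (2.19 ± 1.32, 0.264).

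Gpx4, the lipid peroxide reducing enzyme that restrains ferroptosis (chromosome 10, 80047166 to 80056439, plus strand), passed in no comparison between phases. It stood at 279 ± 30.7 CPM in healthy, 162 ± 97.9 in acute and 236 ± 87.15 in chronic IP (log2 change -0.79 ± 0.32, adjusted p = 0.620, and -0.24 ± 0.34, adjusted p = 1). In input it stood at 290.2 ± 9.53, 306.5 ± 22.3 and 308 ± 32.4 CPM (0.08 ± 0.06, adjusted p = 0.370, and 0.08 ± 0.06, adjusted p = 0.576). Between fractions it was lower in acute IP than in acute input (-0.74 ± 0.25, adjusted p = 0.0351), a call that held in 1 of 5 fits, being 0.141, 0.107, 0.0773 and 0.114 without acute 2, 3, 4 and 5. Voom with library weights, chosen after the data were seen, called it lower in acute IP. Colgalt2 passed in no comparison between phases. It stood at 64.4 ± 19.2, 76.8 ± 12.1 and 81.0 ± 13.6 CPM in healthy, acute and chronic IP (adjusted p = 1 and 0.909) and 56.5 ± 2.33, 56.4 ± 0.357 and 54.7 ± 2.82 CPM in input.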

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

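The tests of carry-over from microglia and leukocytes, from endothelial, mural cells or astrocytes, and of Sting1 from microglia were chosen after the result was seen, as were the offset for gene length and GC content and the fit without the 4 IP libraries with the fewest genes detected.

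Interferon response genes, Ifit3 among them, were higher in acute IP (median log2 change 2.88), and RNA carried over from other cells is a candidate source. Microglia and leukocytes were weighed by the log2 IP to input ratio, which cannot decide whether they are the whole source. The median ratio of the interferon genes was -0.54 (29 genes) against -2.21 for 23 microglia and leukocyte markers, a difference of 1.675 (95% bootstrap interval 0.952 to 2.26). That interval resampled genes, so it does not measure the spread between libraries. The sets also differed in level, with 4 of 16 leukocyte markers at 1 CPM or more in healthy input, and IP libraries missed many genes of low level. C1qa, an abundant microglial gene, stood at 9.22 ± 5.37 CPM in acute and 7.86 in healthy IP while rising from 6.37 to 26.4 in input. Microglia markers passed the preset test (median 0.71, adjusted p = 0.0395) without the 4 IP libraries with the fewest genes, so that a part from microglia stays open. A difference in library complexity is argued against, since all 5 acute libraries had a summed CPM above every healthy library (494 to 737 against 99.8 to 135.5), including those with the fewest genes. Endothelial and mural cells or astrocytes cannot be told apart from expression in the neurons, since the ratio differed from the higher of their medians by -0.581 (-1.35 to 0.570), and 21 of the 29 interferon genes had at least 1 CPM in healthy input. A response of the layer 5 neurons stays open as a hypothesis.

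Cytosolic ribosomal protein genes had a median log2 change of -0.56 in acute IP with 76 of 77 negative, but 0 were called, Rpl9 and Rps3 having adjusted p = 0.338 and 0.389 in edgeR, and the list had adjusted p = 0.339 with an estimated correlation. With the offset for gene length and GC content their median went from -0.56 to -0.28 and differed from that of all genes by -0.255. The offset used the summed exon length of each gene (median 1535 bases for this list), which can exceed that of the transcripts present. Shorter genes had lower changes before the offset. It therefore cannot decide whether such bias is the whole cause, which leaves the bias open as part or all of it. Variation between libraries that the whole list shares is not excluded, with an exact permutation p of 0.1905 on the summed CPM (10000 ± 5608 in acute and 13990 ± 2950 in healthy IP, n = 5 each). Library complexity cannot be told apart from the disease either, since 4 of 5 acute libraries lay below every healthy library and 1 did not. The disease itself stays open and untested.

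Sting1 had reads in 3 of 4 chronic and 0 of 5 healthy IP libraries, and sampling of few molecules may explain it. Among 4410 genes of similar level in input, 12 had that pattern, and 91 of the 126 splits of the 9 libraries gave as many (highest other 104). Carry-over from microglia cannot be told apart, since the log2 IP to input ratio of Sting1 in the chronic phase lay 2.226 above the upper quartile of the microglia markers with a standard error of 1.32. Translation of Sting1 in the neurons stays open.

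Single libraries stood apart from the others of their group in 12 of 96 values (12.5%), where chance gives about 1 in 20, by the gap to the nearest library over the range of the group. In input acute 5 the gap was 0.882 for Gpx4 (346 CPM against 294 to 300.5), 0.780 for summed ribosomal protein genes and 0.711 for mitochondrially encoded genes, and in input acute 4 it was 0.729 for Pygb. In input chronic 4 it was 0.899 for genes detected, 0.881 for H2-K1 (89.3 CPM against 17.1 to 25.7) and 0.857 for MHC class I, and in input healthy 2 it was 0.755 for Ifit3 and 0.733 for interferon genes. In IP it was 0.930 for H2-K1 in chronic 4 (127 against 29.2 to 36.1), 0.773 for Ifit3 in healthy 2 and 0.785 for Pygb in healthy 5.

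Differences between groups were tested directly for the 2 phases in input (1259 genes, Isg15 among them) and for IP against input (Nefm, 1 gene, in the acute phase and 170 in the chronic phase). In the acute phase the median difference between IP and input was 0.19 for layer 5 markers, -0.26 for proteasome subunits, -0.43 for nuclear-encoded oxidative phosphorylation, -1.77 for mitochondrially encoded genes, -0.77 for ribosomal protein genes and 0.24 for presynaptic genes. In the chronic phase it was 0.21 for the heat shock response, 0.089 for proteasome subunits, -1.52 for mitochondrially encoded genes and -0.54 for ribosomal protein genes, and none of these lists passed with an estimated correlation.

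Other splits of the same libraries called fewer genes than the real one in 9 of 11 contrasts, so that only 1 of the splits, the real one, gave as many. Of 100 splits each, the highest other gave 3 against 9 in acute IP, 1 against 26 in chronic IP, 3 against 3230 in acute input, 26 against 449 in chronic input and 12 against 1259 between the phases in input. For IP against input it was 5 against 3587 (60 splits), 512 against 3097 (60) and 0 against 4764 (35), and for the chronic interaction 142 against 170 (60). Between the phases in IP, where edgeR called 0 genes (1145 at an unadjusted p under 0.05, 225 by DESeq2), all 100 splits gave as many, with 1 at the highest. No split can give fewer than 0, so this outcome was fixed in advance and decides nothing. For the acute interaction 13 of 60 splits gave at least its 1 gene, so chance is not excluded, and a split with 281 genes points to a structure of the libraries whose source was not tested.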

How the results depend on the processing

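Of the settings below, voom with library weights, the minimum of 50 CPM, the fit without the 4 IP libraries with the fewest genes detected and the offset for gene length and GC content were chosen after seeing the data, as was the form of the DESeq2 model. Calls in IP acute vs healthy (9) were 188 with DESeq2, of which 47 had a group at 0 counts, 1611 with all 28 libraries fitted together, 23 with only genes higher in IP, 380 with voom, 22 at 50 CPM, 1 without the 4 libraries, 4 with the offset and 1 to 50 leaving out 1 library. In IP chronic vs healthy (26) they were 401, 2550, 110, 53, 157, 40 and 66 in that order, 54 with DESeq2's size factors and 9 to 43 leaving out 1 library. In IP chronic vs acute (0 by edgeR, 1145 at an unadjusted p under 0.05) they were 225, 1762, 36, 60, 15, 0 and 1. Voom moved the median change of all genes in these 3 from -0.04 to 0.16, from -0.03 to -0.14 and from 0.02 to -0.28. In input, all 28 libraries fitted together gave 20, 0 and 0 in place of 3230, 449 and 1259, DESeq2 gave 687 in chronic input, and leaving out 1 library gave 2629 to 3320, 250 to 447 and 784 to 1188. Leaving out 1 replicate, IP vs input, healthy gave 3016 to 3711, IP vs input, acute 2395 to 3138 and IP vs input, chronic 4177 to 5067, and without the 4 libraries these gave 5769, 4533 and 7116. The interactions (acute vs healthy change, IP minus input, 1, and chronic vs healthy change, IP minus input, 170) gave 611 and 1203 with DESeq2, 1364 and 1823 without the 4 libraries, 47 in the chronic phase with no filter, and 0 to 287 and 43 to 148 leaving out 1 replicate. List tests passed in 123 of 316 cases and in 24 with an estimated correlation, and with split controls the shared IP calls (3) had a median of 0 because each phase itself had a median of 0 calls. The sign changed for Colgalt2 between phases in IP (0.08, -0.043 without the 4 libraries, -0.025 to 0.17 leaving out 1 library) and in acute input (-0.024 to 0.016), for Gpx4 between phases in input (-0.055 to 0.053) and for Gpx4 between fractions in the chronic phase (-0.41 to 0.0032), none of them called. Of 3279 comparisons of gene results with alternatives 2754 kept side and direction, 408 lost a call, 103 gained one and 14 changed sign. Fewer libraries and a shared dispersion differ by construction, and otherwise the cause was not tested.

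Each IP library shares its description number with 1 input library. Over 7615 genes 9 of 14 such pairs had a correlation over 0.1 (-0.092 to 0.253). For 9 of 14 IP libraries the input library of their own number correlated best, which goes with pairing. The rest did not match, so whether a number stands for 1 mouse stays open, and the main fits have no block. With a block for that number the interactions gave 0 in the acute and 28 in the chronic phase, where Sting1 had adjusted p = 0.550. With a block for the replicate number in the titles, shared by phases in which IP libraries of 1 number correlated by only -0.163 to 0.143, the counts were 2 in acute and 15 in chronic IP.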

Other observations

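Atg7, the E1-like enzyme of autophagy, had the highest log2 ratio of IP to input under the naming rule in each phase, at 4.78 ± 0.18 in healthy (n = 5 per fraction), 4.57 ± 0.18 in acute (n = 5) and 4.33 ± 0.20 in chronic mice (n = 4). Kalrn, Ubr3 and Sh2d3c also ranked among the first 5 in all 3 phases, Kalrn at 3.82, 3.08 and 2.71, Ubr3 at 3.30, 3.60 and 2.81 and Sh2d3c at 3.25, 3.47 and 2.87. No explanation of these ratios was tested.

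Cldn5, an endothelial tight junction gene, stood at 24.2 ± 16.9 CPM in healthy (SD, n = 5), 6.399 ± 5.34 in acute (n = 5) and 10.3 ± 8.14 in chronic IP (n = 4), and at 4.11 ± 1.10, 4.61 ± 0.462 and 4.36 ± 0.884 in input. Neither change in IP passed edgeR's test (log2 change -1.94 ± 1.20 in acute and -1.23 ± 1.27 in chronic IP). Flt1, another gene of endothelial cells, stood at 8.37 ± 5.53, 4.63 ± 4.30 and 8.27 ± 4.56 CPM in healthy, acute and chronic IP. The lymphocyte gene Cd52 stood at 0 in healthy, 0.893 in acute and 0 in chronic IP.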
